A study of Mus musculus with 20 samples.

How the data were processed

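ATAC-seq was carried out on 20 samples of cultured mouse ER-Hoxa9-Lys-GFP cells, 2 per time point, at 0 h (with E2) and at 9 times after E2 withdrawal. Per the labels' protocols, nuclei of each preparation were divided into 2 transposition reactions, so the replicates may be technical. The authors deposited 1 annotated peak list for each of the 10 time points, which belongs to both replicates of that time, and whether reads or peaks were pooled is not given in the sources used here. Per the submitters' processing notes, BWA, MACS2 2.0 and STAR 2.5 were used, with no role or order given. Whether reads were shifted for the Tn5 cut is not given in the sources used here.

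Per the file headers, the lists were annotated with HOMER's peak annotation program against mm10, whereas the submitters' processing notes name mm9. The coordinates behaved as mm10: of the 0 h peaks, 10607 lay within 1000 bp of a TSS as annotated and 1146 lay between 4000 and 5000 bp away. Coordinates are given as mm10, counted from 1. Gene positions came from the RefSeq table of assembly GRCm38.p6, which is the same sequence as mm10. Each peak has a start, an end, a nearest TSS with its distance in bp, and an annotation, all as deposited. The deposited score of every peak is 0: 0 of the 504887 peaks in the 10 lists had another value, so no ranking of peaks by the authors' score was possible.

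Peaks did not overlap within a list, and the narrowest was 150 bp. Peaks of different lists overlapping by at least 1 bp were merged by chaining into 88351 union regions, and a region was present in a list when it held a peak of it. Its gene and annotation were those of its widest peak. Promoter meant at most 1000 bp from the TSS as deposited. Gained regions were absent at 0, 4 and 8 h and present at 72, 96 and 120 h, and lost regions the reverse. Constant regions were present in all 10 lists. Transient regions were absent at 0, 4, 96 and 120 h and present in at least 2 consecutive lists of 12, 24, 36, 48 and 72 h. Chance overlap was the mean of 100 rotations of a list along its chromosomes. Shares carry 95% Wilson intervals.

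Peaks were assigned to the nearest gene as deposited. All 400 symbols of the 19 gene lists were matched, and 17 had no assigned peak in the lists analysed here. Some genes stand in more than 1 list, such as Cybb in the secondary granule and oxidase lists, Ltf in the secondary granule and estrogen response lists, and Irf8 in the macrophage and transcription factor lists. The value of a list was the log2 ratio of its summed peaks at 120 h and 0 h with 0.5 added to each. Its percentile was taken among 10000 random lists of as many genes, drawn from the 19738 genes with a peak and matched on the decile of union regions per gene. A list outside the central 95% was called high or low. Summed gained and lost regions of each list were ranked among random lists drawn in the same way. The percentile describes these lists and is not a test across replicates.

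Genes were named by a rule fixed before the data were examined: Lyz2 and Hoxa9, up to 4 members per list with the largest difference between gained and lost regions, and the 10 genes with most gained, 10 with most lost and 5 with most transient regions. The part of the rule that ranked regions by score could not be used and was replaced by width. Alternatives covered the overlap needed, the lists used, the sex chromosome Y, the promoter distance, the gene window and the list length, the last by width.

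The region and gene-list steps were tested on simulated data. Of 20000 simulated regions over 10 lists, 100% were put in the right set. These regions were well separated and had no missed or extra peaks, so the result checks the sorting step only. It does not show how regions listed on and off are sorted. Of 100 simulated lists of 25 genes without a shift, among 8000 genes, 5% were called. With a doubled late count and an added late peak at some genes, up to a cap, 100% were called high. The unshifted lists were drawn from the same genes as the random lists, so a rate near 5% was built in. Peaks were kept at the same rate at every simulated gene, so the result checks the calculation only. It does not show how often real lists of unlike promoter share are called. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. Motif content was planned and not analysed here, because it needs the genome sequence.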

Results

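Accessible chromatin was mapped by ATAC-seq, in which the transposase Tn5 cuts and tags open DNA, in mouse ER-Hoxa9-Lys-GFP cells of C57BL/6 origin grown in vitro. These cells carry the homeobox transcription factor Hoxa9 fused to an estrogen receptor and a green fluorescent reporter at the lysozyme locus. Background knowledge of such fusions holds that the ligand E2 (estradiol) keeps the fusion protein active and the cells at an immature myeloid stage. The 20 samples comprised 2 replicates with E2 (0 h) and 2 replicates at each of 4, 8, 12, 24, 36, 48, 72, 96 and 120 h after E2 was washed out. The deposited data gave 1 peak list per time point, with no list per replicate, so no spread between replicates could be computed and no p-value is given. Read depth per sample is unknown, because the lists carry no read counts. Intervals below are 95% Wilson intervals and cover counting error only.

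The first question was how much chromatin was listed as open through the time course. Distal peaks, lying more than 1000 bp from a transcription start site (TSS), made up nearly all of the difference between early and late lists. The list with E2 held 44654 distal and 10607 promoter peaks, and the 120 h list held 14652 distal and 8968 promoter peaks. Promoter peaks were most numerous at 36 h, with 11229, and distal peaks at 24 h, with 51362. Housekeeping genes had 28 promoter peaks at 0 h and 23 at 120 h. All 22 of these genes with a promoter peak at 0 h had one at 120 h and 19 had one at 36 h, but 16 of the 22 had a 0 h promoter peak of at least 747 bp, and wide promoter peaks were mostly kept. The total was 55261 peaks over 30.2 Mb at 0 h, 62559 peaks over 31.5 Mb at 24 h, 46837 over 26.0 Mb at 72 h, 29806 over 17.9 Mb at 96 h and 23620 over 15.4 Mb at 120 h. The promoter share was 19.2% (18.9 to 19.5%) at 0 h, 32.1% (31.6 to 32.7%) at 96 h and 38.0% (37.4 to 38.6%) at 120 h. Median peak width was 474 bp at 0 h, 413 bp at 36 h and 617 bp at 120 h. A difference in read number between lists would alter these totals, and read numbers were not analysed here.

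**Figure D1:**
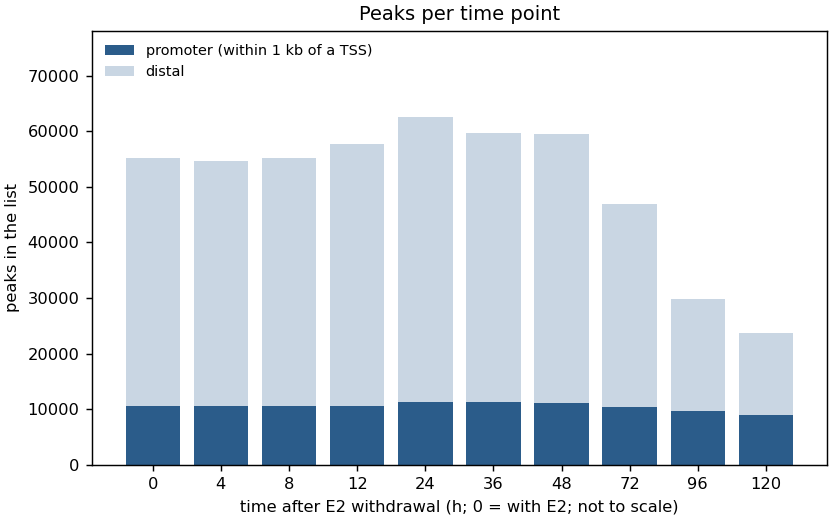
Number of peaks in each deposited list (y axis, peaks) by time after E2 withdrawal (x axis, h, categories not spaced to scale), split into promoter peaks within 1000 bp of a TSS (dark) and distal peaks (light). Distal peaks went from 44654 at 0 h to 14652 at 120 h, against 10607 and 8968 promoter peaks; each bar is 1 list without replicate error.

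The next question was which sites open in the presence of E2 were still listed later. Promoter sites were kept far more often than distal sites: at 120 h, 75.0% of the 0 h promoter peaks and 22.5% of the 0 h distal peaks overlapped a listed peak by at least 1 bp. Up to 24 h both classes were mostly kept, with 89.1% of promoter and 79.0% of distal peaks overlapped at 24 h. At 72 h the values were 83.3% and 54.3%. Over all 0 h peaks, 82.8% (82.5 to 83.1%) were overlapped at 4 h, 80.9% (80.6 to 81.3%) at 24 h, 73.8% (73.5 to 74.2%) at 48 h, 59.9% (59.5 to 60.3%) at 72 h, 40.0% (39.6 to 40.4%) at 96 h and 32.6% (32.2 to 33.0%) at 120 h. Peaks rotated at random along their chromosomes overlapped 2.33% of the 0 h peaks at the 4 h list's size and 1.13% at the 120 h list's size, as means of 100 rotations. Peaks without a 0 h counterpart made up 16.2% (15.9 to 16.6%) of the 4 h list, 28.1% (27.7 to 28.4%) of the 24 h list, 30.8% (30.5 to 31.2%) of the 48 h list and 25.03% (24.5 to 25.6%) of the 120 h list. With every list reduced to its 23620 widest peaks, an alternative chosen after the data were seen, 53.2% of the 0 h peaks were overlapped at 120 h. The share without a 0 h counterpart was then 32.7% at 48 h, 43.4% at 96 h and 46.8% at 120 h. With the widest 50% of each list, chosen in the same way, it was 35.5%, 24.3% and 21.1%, so its course after 48 h depended on how lists were cut.

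Lists close in time shared most of their regions, and the boundary with the least sharing lay between 72 and 96 h. Overlapping peaks of all lists were merged into 88351 union regions. The share of regions present in both of 2 consecutive lists was 0.72 for 0 and 4 h, 0.70 for 4 and 8 h, 0.71 for 8 and 12 h, 0.69 for 12 and 24 h, 0.72 for 24 and 36 h, 0.73 for 36 and 48 h, 0.64 for 48 and 72 h, 0.53 for 72 and 96 h and 0.68 for 96 and 120 h. The lists of 0 and 120 h shared 0.29. On covered bases, the shared fraction was 0.52 between 72 and 96 h and 0.68 between 36 and 48 h. The 72 and 96 h lists held 46837 and 29806 peaks, and such a difference in length lowers the share they can reach. With every list cut to the same number of widest peaks, chosen after the data were seen, 72 and 96 h shared 0.57. This was still the lowest value of consecutive lists. The next lowest values were 0.61, for 12 and 24 h and for 48 and 72 h. The size of the drop between 72 and 96 h therefore depended on list length.

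**Figure D2:**
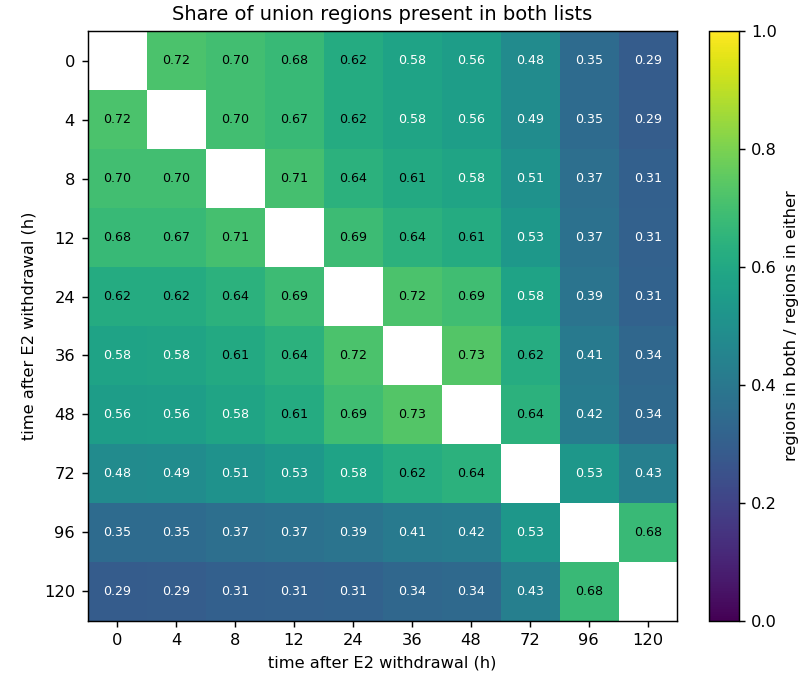
Share of union regions present in both lists among those present in either (colour and number, 0 to 1) for every pair of time points (both axes, h after E2 withdrawal). At the deposited list lengths, neighbouring lists up to 48 h share 0.69 to 0.73, whereas 72 and 96 h share 0.53 and 0 and 120 h share 0.29. With lists cut to equal length by width (not shown), 72 and 96 h share 0.57 and 12 and 24 h share 0.61.

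Regions were then sorted by when they were present. Gained regions were absent at 0, 4 and 8 h and present at 72, 96 and 120 h, and lost regions the reverse. Neutrophil genes of 2 lists fixed beforehand held more gained regions than all of 10000 random gene lists matched for number of regions, a comparison chosen after the data were seen. The secondary and tertiary granule list had 14 gained regions at 10 of its 18 genes (central 95% of random lists 0 to 5), and the neutrophil surface and chemotaxis list had 21 at 14 of 28 genes (1 to 11). Their lost regions, 1 and 11, lay below the central 95% (4 to 17 and 17 to 40). The NADPH oxidase list with 5 gained regions and the myeloid transcription factor list with 19 lay at the upper limit of the central 95%. Cd177, Arg2 and Cybb of the granule list had 2 gained regions each, as did Cd14, which stands in both the surface list and the macrophage and monocyte list. The progenitor and stem cell list had 38 lost regions at 17 of 25 genes, inside the central 95% (18 to 44), and 2 gained. Among its members, 6 lost regions were assigned to Angpt1, which encodes a ligand of the Tie2 receptor, 5 to Ikzf2, a zinc finger transcription factor, and 3 to Meis1, the homeobox partner of Hoxa9. Over the genome 2100 regions were gained, 11064 were lost and 12178 were present in all 10 lists. A further 8529 regions were transient, being absent at 0, 4, 96 and 120 h and present in at least 2 consecutive lists from 12 to 72 h. Gained regions were 7.86% promoters (6.78 to 9.09%), lost regions 4.48% (4.11 to 4.88%), transient regions 3.79% (3.40 to 4.21%) and constant regions 43.3% (42.4 to 44.2%). Intergenic sites made up 45.4% of gained, 47.2% of lost and 29.1% of constant regions, and introns 43.4%, 44.3% and 29.6%. These counts depended on list length and on the lists used. With lists of the 23620 widest peaks, 2463 regions were gained and 3181 lost, and with the widest 50% of each list, 628 and 5105. Transient regions numbered 2314 and 5445 under these 2 cuts, and constant regions 7205 and 6029. Ignoring the 120 h list gave 3308 gained and 11193 lost regions, and 2 early and 2 late lists gave 3519 and 24406.

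By count per list, the unbroken presence of gained regions began most often at 24 h, which was also the longest list. Lost regions were most often last listed at 48 h, the last list that their definition allows. The lists were unevenly spaced, with 48 and 72 h farther apart than 8 and 12 h. The counts are therefore not rates and do not show when change was fastest. For 445 of the gained regions (21.2%) the unbroken presence up to 120 h began in the 12 h list, for 643 (30.6%) at 24 h, for 293 (13.95%) at 36 h, for 281 (13.4%) at 48 h and for 438 (20.9%) at 72 h. Of the lost regions, 1938 (17.5%) were last present in the unbroken run at 8 h, 2059 (18.6%) at 12 h, 1867 (16.9%) at 24 h, 1199 (10.8%) at 36 h and 4001 (36.2%) at 48 h. Transient regions were most often listed at 36 h, with 6685 of them present (78.4%), against 1822 (21.4%) at 8 h and 4010 (47.0%) at 72 h.

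**Figure D3:**
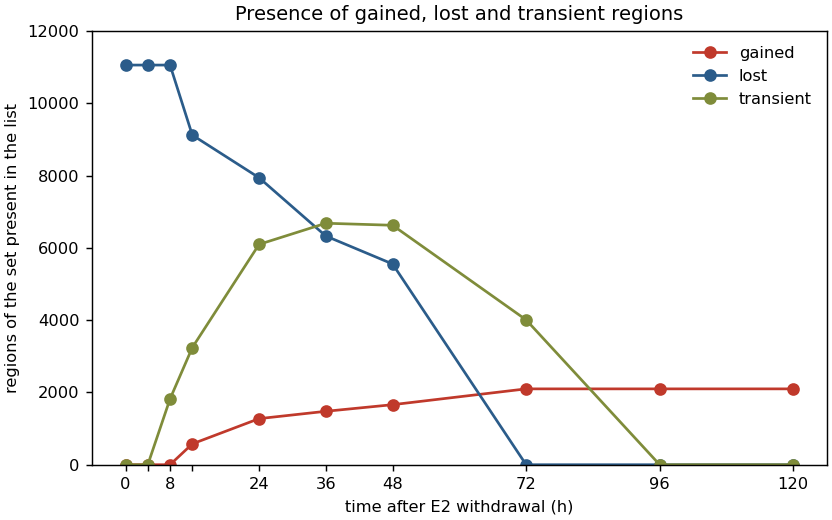
Number of gained, lost and transient regions present in each list (y axis, regions) against time after E2 withdrawal (x axis, h). The definitions fix gained regions at 0 up to 8 h and lost regions at 0 from 72 h; between them, 1276 of 2100 gained regions are present at 24 h and 5557 of 11064 lost regions at 48 h.

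Gene lists fixed before the data were examined were compared by the peaks assigned to their members at 120 h and at 0 h. The secondary and tertiary granule list, built around proteins that neutrophils store late in maturation but not limited to them, went from 31 peaks to 41. At the deposited list lengths it was the only 1 of the 19 lists with more peaks at 120 h, and it lay above all of 10000 random gene lists matched for number of regions (log2 ratio 0.40, central 95% of random lists -1.96 to -0.64). Of its 18 genes, 10 had more peaks at 120 h, 6 had fewer and 2 had as many. The neutrophil surface and chemotaxis list (107 and 102 peaks, log2 ratio -0.07) and the inflammatory and NF-kB list (122 and 94 peaks, log2 ratio -0.37) also lay above all random lists. Of the surface genes, 11 had more peaks at 120 h, 11 had fewer and 6 had as many. Of the inflammatory genes, 6 had more, 14 had fewer and 8 had as many. Random lists had medians between -1.32 and -1.07. The inflammatory list had 10 gained and 24 lost regions, both inside the central 95% of random lists (2 to 12 and 19 to 44). The direction of list ratios depended on list length: with lists of the 23620 widest peaks, 11 of the 19 log2 ratios were above 0. Among them were 2.13 for secondary granule, 1.11 for neutrophil surface and 1.05 for inflammatory genes. With equal totals at both times, ratios on both sides of 0 follow from the cut. These values therefore cannot be set beside the ratios at the deposited list lengths. With 96 h in place of 120 h the neutrophil surface list was above 0 too, at 0.23. The neutrophil surface list was above the central 95% at 8 h already (percentile 99.9), the secondary granule list from 24 h on (99.3), and the inflammatory list at 8 h (98.5) and from 36 h on. The call of these 3 lists held in all 6 alternatives of gene assignment, time point and list length.

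**Figure D4:**
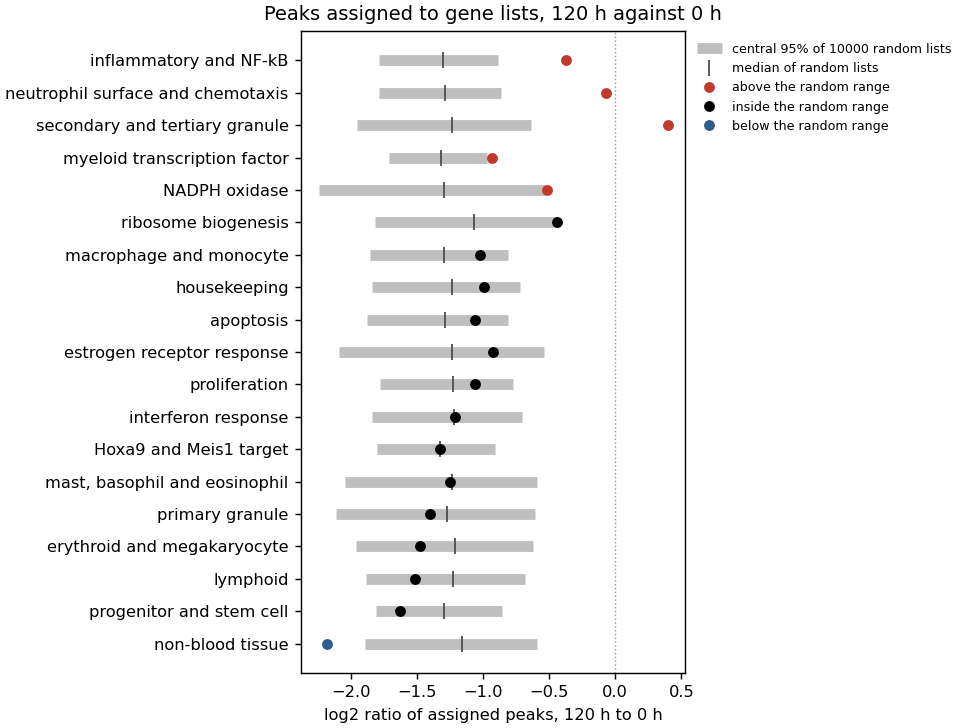
Log2 ratio of peaks assigned to each of 19 gene lists, 120 h to 0 h with 0.5 added to both (x axis), with the central 95% (grey bars) and median (ticks) of 10000 random lists matched for size and regions per gene. Secondary and tertiary granule genes sit at 0.40 and neutrophil surface genes at -0.07, above their random ranges, and non-blood tissue genes at -2.18, below theirs. With distal peaks only (not shown), the non-blood list lies inside its random range.

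Single genes of the granule and surface lists showed when the sites came and went. Cd177, a neutrophil surface glycoprotein (chromosome 7, 24743983 to 24760334 in mm10), had no peak up to 12 h, 1 from 24 to 48 h and 2 from 72 h on. Its regions at 24753493 to 24754013 and 24758518 to 24758897 were intronic. Arg2, an arginase, had no peak up to 12 h and 2 from 24 h to 120 h, but not the same 2 throughout. Of its intronic gained regions on chromosome 12, that at 79131956 to 79132676 was listed from 24 h and that at 79140688 to 79141474 from 72 h, and a further region was transient. Cybb, the membrane subunit of the phagocyte oxidase, had 0 peaks at 0 h, 1 from 4 to 36 h, 2 at 48 h, 4 at 72 and 96 h and 3 at 120 h. Ltf, which encodes lactoferrin, had 0 peaks at 0 and 4 h, 1 at 8 h, 0 from 12 to 36 h and 1 at 48 h. It had 3 at 72 h, 3 at 96 h and 4 at 120 h, with a gained intronic region at 111037206 to 111037938 on chromosome 9. Itgam, the integrin CD11b, had 6 peaks at 0 h, 10 at 48 and 72 h and 7 at 120 h. Cd14 in the surface list had 0 peaks up to 8 h, 4 from 24 to 72 h and 2 at 120 h. One of its gained regions covered the 5' UTR, 210 bp from the TSS (chromosome 18, 36726283 to 36726967). Pilra, an inhibitory receptor, had 1 peak at 0 h, 7 from 48 to 96 h and 5 at 120 h, and Cxcr4, the receptor that retains neutrophils in marrow, had 17 at 0 h, 27 at 36 h and 12 at 120 h.

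Genes of the primary granules, which neutrophils fill at the promyelocyte stage, had fewer peaks late at the deposited list lengths. The list went from 51 peaks at 0 h to 19 at 120 h, with 11 of 12 genes lower and Bpi equal at 1 peak. Its log2 ratio of -1.40 stood at percentile 36.9 of random lists, so it was no lower than that of other genes. With lists of the 23620 widest peaks its log2 ratio was 0.16, at percentile 65.4. With promoter peaks only (10 and 5), the list stood below the central 95%, at percentile 2.44, and with distal peaks only at 53.3. Elane, which encodes neutrophil elastase, had 1 peak at 0 h, 2 from 4 to 48 h, 1 at 72 h and 0 at 96 and 120 h. Its lost region lay -1732 bp from the TSS (chromosome 10, 79884312 to 79884841). Its neighbour Prtn3 and the gene Ctsg, both serine proteases and both chosen after their values were seen, had 4 peaks in every list up to 72 h. At 96 h Prtn3 had 0 and Ctsg 1, and at 120 h both had 0. The difference in log2 ratio between the secondary and primary lists was 1.80, against -1.04 to 0.98 for the central 95% of 10000 random divisions of the same 30 genes. It was 1.73 with distal peaks only and 1.30 with the 96 h list. This division was chosen after the data were seen. Lyz2, the lysozyme gene that carries the reporter (chromosome 10, 117277541 to 117282272), had 3 peaks from 0 to 36 h, 5 at 48 h, 4 at 72 h, 1 at 96 h and 2 at 120 h. No peak of the lists analysed here was assigned to Hoxa9 or overlapped it, so that locus is not described.

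**Figure D5:**
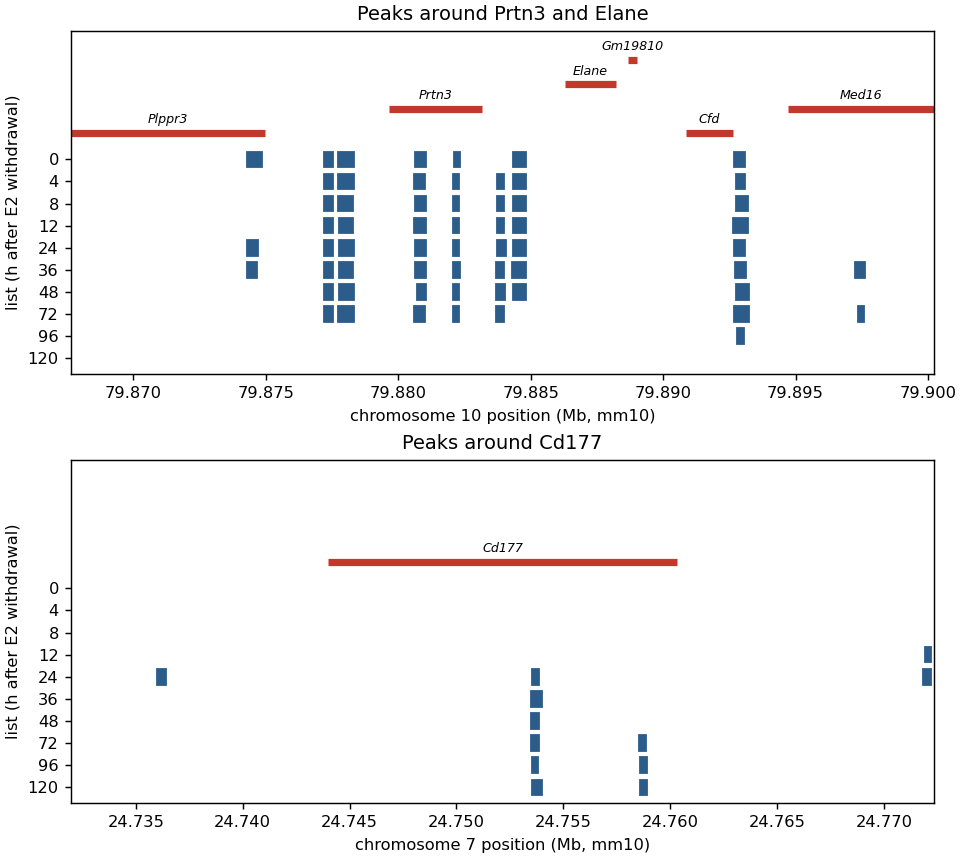
Peaks (boxes) in each list (rows, h after E2 withdrawal) along chromosome 10 around Prtn3 and Elane and along chromosome 7 around Cd177 (x axes, Mb, mm10), with RefSeq genes in red. The 4 peaks of Prtn3 are listed from 0 to 72 h and not at 96 or 120 h, while both Cd177 peaks are listed from 72 h on.

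Lists of stem cell and alternative lineage genes had fewer peaks at 120 h, in the main setting mostly within the range of random lists. The progenitor and stem cell list went from 146 to 47 peaks (log2 ratio -1.62, percentile 10.2), with 24 of 25 genes lower. It stood below the central 95% at 24 h (percentile 0.89) and with the 96 h list (0.67), and at 120 h with lists of the 23620 widest peaks (1.72). At 24 and 36 h the lymphoid list (1.38 and 2.47) and the interferon response list (1.62 and 2.10) stood below it too. Angpt1 had 17 peaks at 0 h and 4 at 120 h, Ikzf2 had 15 and 3, Erg, an ETS factor, had 12 and 4, and Meis1 had 13 and 4. The Hoxa9 and Meis1 target list went from 216 to 86 peaks (log2 ratio -1.32, percentile 50.6). It shares 7 genes with the progenitor list. Trib2, a pseudokinase gene, had 16 peaks at 0 h and 4 at 120 h, and Camk2d had 11 and 2. The lymphoid list had 61 and 21 peaks (percentile 18.0), the erythroid and megakaryocyte list 51 and 18 (22.8) and the mast, basophil and eosinophil list 53 and 22 (47.7). With promoter peaks only, the erythroid list (10 and 4 peaks, percentile 1.45) and the mast cell list (5 and 2 peaks, 1.88) stood below the central 95%. These are few peaks, and with distal peaks only the lists stood at 56.7 and 79.3. Tcf7, a T lineage factor, had 7 peaks at 0 h and 0 at 120 h, and Gata2 had 6 and 2. The non-blood tissue list had 38 and 8 peaks (log2 ratio -2.18, percentile 0.52) and was the only list below the random range at 120 h. It was below that range at 96 h too (percentile 2.44). Tbx5, a heart and limb factor, had 3 peaks from 0 to 12 h and 0 from 48 h on, and Foxa2, an endoderm factor, had 5 at 0 h and 0 from 72 h on. Only 1 of its 38 peaks at 0 h was a promoter peak, and random lists were not matched for promoter share. With distal peaks only, the non-blood list stood at percentile 10.6, inside the random range.

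Most myeloid transcription factor and macrophage genes had fewer peaks at 120 h, 31 of 36 and 19 of 23. The myeloid transcription factor list had 293 and 153 peaks (log2 ratio -0.94, percentile 98.5), above the central 95%. Klf6, a Kruppel-like factor, had 8 peaks at 0 h and 9 at 120 h with 2 gained regions, whereas Irf8, the factor of monocyte fate, had 18 and 1, and Runx1 had 27 and 13. The macrophage and monocyte list had 159 and 78 peaks (percentile 85.8), with Maf at 29 and 16 and Csf1r, the receptor of macrophage growth factor, at 4 and 3. With promoter peaks only (14 and 7), this list stood at percentile 0.84. With distal peaks only (145 and 71) it stood at 95.5, and with 96 h in place of 120 h at 96.4, both inside the central 95%. The NADPH oxidase list had 36 and 25 peaks (log2 ratio -0.52, percentile 97.8), above the central 95%, with Ncf4 at 5 and 5. The calls of the transcription factor and oxidase lists each held in 2 of 6 alternatives.

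The other lists lay inside the random range at 120 h in the main setting. Proliferation genes had 107 and 51 peaks (percentile 75.5), with Mki67 at 9 and 3 and Cdk6 at 17 and 3. Ribosome biogenesis genes had 30 and 22 (97.49, at the limit), and stood above the central 95% with promoter peaks only (98.47) and with 4 h in place of 0 h (98.72). They stood inside it with distal peaks only (17 and 6, 67.7), with the 96 h list (94.2) and with equal-length lists by width (94.3). Apoptosis genes had 103 and 49 (80.5), interferon response genes 70 and 30 (51.6), housekeeping genes 90 and 45 (81.9) and estrogen receptor response genes 29 and 15 (79.6). Among interferon genes, Mx1 had 6 peaks at 24 h as at 0 h. At 120 h Mx1 and Ifit1 each had 1 peak, against 6 at 0 h. Among inflammatory genes Tnip1, an inhibitor of NF-kB signalling, had 7 peaks at 0 h and 4 at 120 h, and Il6 had 10 and 3. Greb1, an estrogen receptor target, had 5 peaks at 0 h and 1 at 120 h, and Esr1 had 6 and 4.

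Single genes had up to 6 gained, 24 lost and 11 transient regions. Notch2, a receptor of the Notch pathway, had 6 gained and 4 lost regions among 22, with 12 peaks at 0 h and 14 at 120 h, and March1, a ubiquitin ligase gene, had 5 gained and 1 lost. One of the gained regions lay -82 bp from a March1 TSS (chromosome 8, 66385921 to 66386537) and was listed from 36 h on. Nr3c1, the glucocorticoid receptor, Pag1, an adaptor of Src kinases, and Tank, a regulator of NF-kB signalling, had 4 gained regions each, with 2, 0 and 1 lost. Nr3c1 had 4 peaks at 0 h, 13 at 24 h and 7 at 120 h. The noncoding gene Gm30214 had 24 lost regions, Rprl1 had 10, and Phactr3, Afap1, Rbms3 and Efna5 had 9 each. Phactr3 had 15 peaks at 0 h and 0 at 120 h. Sipa1l1 had 11 transient regions, with 13 peaks at 0 h, 27 at 48 h and 8 at 120 h, and Oxr1 had 8. By width, a rule chosen after the data were seen, the widest gained peak at 120 h lay -400 bp from the Fbxl20 TSS (chromosome 11, 98149321 to 98150711, 1391 bp). The widest lost peak at 0 h was intronic and assigned to Dlg2 (chromosome 7, 92180484 to 92182530, 2047 bp).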

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

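The test on B2 elements was chosen after the shares of B2 annotation had been seen. The repeat class in the detailed annotation of each peak, which the comparisons above did not use, was more frequent in some lists after E2 withdrawal than with E2. Peaks annotated to LTR elements (remnants of endogenous retroviruses) made up 8.47% (95% interval 8.25 to 8.70%) of the 48 h list and 7.20% (6.99 to 7.42%) of the 0 h list. LINE elements reached 3.26% at 72 h, against 2.73% at 0 h, and SINE elements 6.26% at 48 h, the latter against 5.87% (5.68 to 6.07%) at 0 h.

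The late lists had few peaks on B2 elements, a family of mouse SINEs: 2300 at 0 h (4.16%), 2561 at 48 h (4.30%), 1211 at 72 h (2.59%), 206 at 96 h (0.69%) and 88 at 120 h (0.37%). Weak peaks of long lists were tested as a source of the LTR excess, with peak width standing for strength. Among the widest 50% of peaks the LTR share was still 6.31% (6.04 to 6.59%) at 48 h, against 5.36% (5.10 to 5.63%) at 0 h. This cut reached narrower peaks at 48 h (list median 421 bp) than at 0 h (474 bp), so it cannot exclude weak peaks as the source. The LTR share of the widest 50% was lower than at 0 h in the late lists, with 3.82% (3.53 to 4.14%) at 96 h and 2.93% (2.64 to 3.25%) at 120 h. Over all peaks at 120 h the LTR share was 6.66% (6.34 to 6.98%). The late lists held wider peaks and a larger promoter share, and LTR shares were not compared among distal or width-matched peaks. Narrow width was tested for the B2 peaks (median 277 bp at 0 h): of 2282 distal B2 peaks at 0 h, 3.37% (2.71 to 4.20%) were kept at 120 h, against 13.7% of other distal peaks of the same width, a difference of -10.3 percentage points. At 48 h the B2 peaks were kept in 69.0% and the width-matched others in 65.9%, and at 72 h the difference was -6.85 points. A difference in read length or in the handling of multiply mapping reads between early and late libraries stays open, as does closing of these elements as the cells matured without E2, which could not be tested with peak lists alone.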

How the results depend on the processing

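Alternatives using peak width, and those ignoring both the 96 h and 120 h lists, were chosen after the data were seen. Requiring 50% overlap or the peak centre gave 2110 gained, 11092 lost, 12165 constant and 8568 transient regions, and leaving out chromosome Y gave 2100, 11063, 12168 and 8528. Both overlap shares at 120 h stayed inside the 95% interval of the main value under these 3 settings. Gained regions numbered 3519 with 2 early and 2 late lists, 3308 ignoring the 120 h list, 8314 ignoring the 96 h and 120 h lists and 628 with the widest 50% of each list. Lost regions numbered 24406 with 2 early and 2 late lists, 3181 with equal-length lists by width and 5105 with the widest 50%. Constant regions numbered 24243 ignoring the 96 h and 120 h lists, 7205 with equal-length lists and 6029 with the widest 50%. Transient regions numbered 17795 with 2 early and 2 late lists, 12799 ignoring the 96 h and 120 h lists, 2314 with equal-length lists and 5445 with the widest 50%. Fewer lists or fewer peaks change these counts by construction. The share of 0 h peaks overlapped at 120 h was 53.2% with equal-length lists and 34.0% with the widest 50%, and the share of 120 h peaks without a 0 h peak was 46.8% and 21.1%. Promoter percentages with a limit of 500 bp, a limit of 2500 bp and the annotation word were 6.67, 13.5 and 6.19 for gained, 2.87, 9.31 and 2.87 for lost, 41.8, 47.3 and 30.4 for constant, and 2.16, 9.10 and 2.26 for transient regions, and constant regions had the highest share throughout. Of 114 alternative percentiles of gene lists, 96 kept their call. With promoter peaks only, percentiles went to 10.54 for NADPH oxidase, 0.84 for macrophage and monocyte, 49.56 for myeloid transcription factor and 54.34 for non-blood tissue (1 promoter peak at each time), each on the other side of the random median, and to 2.44 for primary granule, 98.47 for ribosome biogenesis, 1.45 for erythroid and megakaryocyte and 1.88 for mast, basophil and eosinophil. Within 50 kb, NADPH oxidase stood at 96.54 and myeloid transcription factor at 91.66. With 4 h in place of 0 h, NADPH oxidase stood at 97.12 and ribosome biogenesis at 98.72. With 96 h in place of 120 h, progenitor and stem cell stood at 0.67 and myeloid transcription factor at 95.36. With equal-length lists, NADPH oxidase stood at 93.84, progenitor and stem cell at 1.72 and myeloid transcription factor at 90.34. With distal peaks only, non-blood tissue stood at 10.62. The cause of these shifts was not tested. At the other times 31 of 80 alternative overlap shares left their interval, all with lists reduced by width. Alternatives using the score, listed before the data were examined, and those on motifs, were not run, because every score is 0 and no genome sequence was used. No paired analysis was possible because each list holds 1 peak set for both replicates. Unknown read depth limits all counts at 96 and 120 h.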

Other observations

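The test within the widest peaks at 0 h, the shuffles that keep list totals and the description of antigen receptor loci were chosen after the data were seen. The intervals of variable gene segments of antigen receptors, which are rearranged in lymphocytes, were looked at because Gm30214 and Rprl1 had many lost regions. The interval of the T cell receptor alpha and delta variable segments (chromosome 14, 52427967 to 53977678), which contains regions assigned to Gm30214, held 121 union regions. Of these, 28 were lost and none was gained. In this interval 71 regions were present at 0 h, 86 at 24 h, 42 at 72 h, 9 at 96 h and 4 at 120 h. The immunoglobulin kappa variable interval (chromosome 6, 67555636 to 70704177), which contains regions assigned to Rprl1, held 51 regions, with 14 lost and none gained, and its number declined earlier: 42 were present at 0 h, 30 at 4 h, 23 at 24 h, 8 at 72 h and 4 at 120 h. In the immunoglobulin heavy chain variable interval 16 of 170 regions were lost, and in the T cell receptor beta variable interval 6 of 39. Over all regions 11064 of 88351 were lost, and the first 2 intervals were chosen for their lost regions, so their larger shares carry no weight as a test.

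The late lists were short of distal peaks, and part of this may be a loss of weaker peaks. With all 0 h peaks divided by width into 5 equal bins, 22.3% of the 660 promoter peaks in the narrowest bin and 42.1% of the 4622 distal peaks in the widest were kept at 120 h, a difference of -19.8 percentage points, in line with narrow peaks dropping out first. Width did not account for the difference between promoters and distal sites, since within the widest bin 87.4% of the promoter peaks were kept, 45.3 points more than of the distal peaks. A loss of sensitivity at all sites alike stays open: 100% (95% interval 85.1 to 100%) of the 22 housekeeping promoters were kept, but 16 of them had a 0 h peak in the widest bin, where most promoter peaks stay listed, so the bound set beforehand could not exclude it. Fewer cells or reads behind the late lists and closing of distal sites after E2 withdrawal cannot be told apart without read totals: the share of peaks without a 0 h peak was 8.78 points higher at 120 h than at 4 h, but this depended on the cut of lists (46.8% against 21.6% with equal-length lists, 21.1% against 20.5% with the widest 50%).

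The transient regions may be weak sites listed where lists were longest, sites open for part of the course, or both. With equal-length lists by width their number was 2314 in place of 8529, but lost regions went down in similar proportion, from 11064 to 3181, and with the widest 50% of each list there were 5445 transient and 5105 lost regions, so weak sites are neither shown nor excluded as their source. Chance listing near the threshold, independent from list to list, is argued against by their order: of 9123 regions absent at 0, 4, 96 and 120 h and present in 2 to 4 of the 5 middle lists, 71.1% were present in an unbroken run, against at most 37.7% in 100 shuffles within regions. In 100 shuffles that also kept the number of regions per list the highest share was 58.5%, which is 12.6 points lower. Weak sites listed in libraries prepared close together and a passing stage of the cells between 12 and 72 h both stay open and were not tested.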
